A study of Mus musculus with 9 samples.

How the data were processed

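RNA of 9 mouse cell samples was labelled with 1 dye (Cy3) and hybridised once each, per the labels. The deposited scanner files hold intensity values made by the authors with Agilent Feature Extraction 8.5.1.1, per the file headers. The column used is that program's processed signal, an intensity on a linear scale after its background subtraction, and it can be at or below 0 (18% to 23.5% of probes on an array). A spot counts as well above background when the program says so, with a background multiple of 2.6 per the file headers. The series' value table was set against the scanner files: for probes spotted once it held the same processed signal within 0.5%, so it is linear, not centred and not a ratio. Its column medians were 17 for ES, 14.6 for MEF, 15.2, 19.6, 16.7 and 14.3 for the 4-factor, 10-factor and 3-factor iPS clones 1 and 2, 8.97 for the NIH3T3 HRasV12 cells and 10.9 for the unselected MEF. It was used as an alternative. The 75th percentile of the signal was between 167 and 300.

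The arrays held 20868 gene probes on 21318 spots, and 736 control spots were left out, as were spots called outliers by the program (0 to 9 an array). Repeated spots of the 50 probes spotted 10 times were averaged. Each array was scaled to its 75th percentile, values were then set to a floor at 3.63% of that percentile (-4.78 on the log2 scale), and log2 was taken. Values at the floor have no order. Between 39.8% and 49.3% of probes on an array were at the floor. A gene whose probes were not well above background on any array of the dimmer side has only a bound: the mean of the brighter side against, per array, the higher of the lowest signal well above background and the probe's own. The floor is the highest of these lowest signals over the 9 arrays, so a bound can exceed the difference taken at the floor. Bounds are written as at least N-fold. The same holds for a brighter side that is saturated.

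Probe names came from RefSeq accessions through a reference table (14227 probes), from other RefSeq accessions of the probe (64), from RIKEN clone names (1522), from symbols in the deposited descriptions (503 found in the table and 172 not), and for 21 probes from gene names written in words in the description, a list made after the files were seen and from descriptions alone. This gave 16509 probes of 15766 genes, and 4359 probes were left unnamed. A gene with several probes is given by its brightest on average. No genome build is given in the sources used here.

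Groups follow the labels. The 4 iPS clones were compared with the 4 fibroblast-derived samples, with MEF alone, with ES alone, and 3-factor with 4- and 10-factor clones. Probes were kept that were well above background on at least 50% of the arrays of a compared group. Tests were limma 3.58.1 (lmFit and eBayes, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 23 gene lists, fixed before the files were seen, were tested with camera at its preset correlation, with an estimated correlation and with fry, which asks whether a list's genes move one way on balance. They covered pluripotency, candidate and transduced factors, fibroblast matrix, mesenchymal transcription factors, epithelium, HOX, trophectoderm, primitive endoderm, neural, mesoderm and germ cell genes, imprinted genes, Ras and MAPK output, proliferation, senescence and p53, Myc targets, chromatin, interferon response, other cell types, glycolysis, X and Y genes, and housekeeping and stress. Comparisons of single arrays count probes at least 5-fold apart, with the brighter one well above background, and set a list's median against 10000 random lists matched on signal.

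The lists not called in a comparison had these camera adjusted p. For the clones against fibroblast-derived samples they were 0.0749 for candidate factors, 0.797 for transduced factors, 0.394 for HOX, 0.489 for trophectoderm, 0.0656 for primitive endoderm, 0.404 for neural, 0.797 for mesoderm, 0.141 for germ cells, 0.406 for imprinted, 0.265 for Ras and MAPK output, 0.0574 for senescence and p53, 0.201 for interferon, 0.489 for other cell types, 0.797 for glycolysis, 0.0574 for X and Y genes and 0.797 for housekeeping and stress. With scan as a block, where only the 4- and 10-factor clones and MEF of scan 1 give the difference, 3 of these were called: candidate factors (median 2.12, camera adjusted p = 0.0079), HOX (-1.13, camera adjusted p = 0.00118) and interferon (-2.43, camera adjusted p = 5.57e-10). In the neural list the median (-0.02) and mean (0.81) differed in sign, as they did in the glycolysis (-0.16 and 0.23), housekeeping and stress (-0.12 and 0.2) and trophectoderm lists (-0.14 and 0.62). Scans were taken from the file headers: ES, MEF and the 4- and 10-factor clones were in scan 1, the 3-factor clones in scan 2, the NIH3T3 HRasV12 cells and the immortalised MEF line in scan 3 and the unselected MEF in scan 4. Each slide held 1 array, so slide could not be a block.

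Named genes were chosen by a rule written before the files were seen: per comparison the 10 largest rises and 10 largest falls that passed the test, with all arrays of one side apart from those of the other, a gene symbol, and the bright side well above background on all its arrays. For single arrays they were the 10 largest differences each way. List members can be named as examples, and Fbxo15, Pou5f1, Sox2, Klf4, Myc and Nanog are named in any case. List members given as examples were picked after their values were seen.

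On simulated data with 200 changed probes, limma recovered 10.4% of 2-fold, 62.7% of 4-fold and 84.8% of 8-fold changes for the clones against fibroblast-derived samples, 10.4%, 28.4% and 42.4% against MEF, 1.5%, 13.4% and 36.4% against ES, and 0%, 35.8% and 54.5% for 3-factor against the other clones. The changed probes were drawn from the brighter ones, with independent normal noise, so these rates do not cover probes near the floor. The lone MEF or ES array was simulated with the spread of the clones. The alternatives tried, besides leaving out each sample, were quantile and median scaling, normexp background correction with an offset of 50, the value table, other filters and fold thresholds, scan as a block, other variance models and, added after the data were seen, other treatment of the floor, scan 1 alone and the 3-factor pair averaged. For the gene lists, median scaling and scan as a block were also added after the data were seen. Results that need certain items withheld from this text, among them the comparison of the immortalised MEF line with MEF, are not reported here.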

Results

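The series measured RNA of 9 mouse cell samples on single-colour Agilent arrays, with 1 hybridization for each sample. It asked how cells that became like pluripotent stem cells after retroviral transfer of defined factors compare with embryonic stem (ES) cells and with the fibroblasts they came from. There were 4 clones of such induced (iPS) cells, made from mouse embryonic fibroblasts (MEF) with 4 factors (1 clone), 10 factors (1 clone) and 3 factors (2 clones), and kept under drug selection for 16 days. The selection marker sits in the Fbxo15 gene (Fbx15 in the labels), which is active in ES cells. The comparison cells were 1 ES line and 1 MEF preparation, both labelled as lacking Fbx15, and 3 other fibroblast-derived samples. These were MEF that received 4 factors without selection and gave no iPS clones, NIH3T3 fibroblasts transformed with an active HRas mutant (HRasV12), and an immortalised line of wild-type MEF that is used here only as a member of the group. The labels do not name the factors. The gene list called transduced factors below is 4 genes fixed beforehand, and whether they are the factors given cannot be read from the labels. Between 52.4% and 59.6% of the probes on an array were well above background. Nothing says that samples of a class came from separate cultures, so p-values measure only the spread between these samples, and the number of arrays limits the precision.

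Fbxo15 was bright in ES, at 1.24 on the log2 scale relative to the array's 75th percentile, and in the iPS clones, at -0.55 with 4 factors, -0.46 with 10 factors, and 1.35 and 1.05 with 3 factors. It was not well above background in any of the 4 fibroblast-derived samples. The ES line is labelled as lacking this gene. The files give the probe on chromosome 18 at 85149104 to 85149163, with no genome build, and whether this lies in the replaced part is not given in the sources used here, so the probe checks no label. Pou5f1 (Oct4), a transcription factor of pluripotent cells, was at 1.87 in ES, between 0.8 and 1.14 in the iPS clones, and not above background in MEF. Nanog, another such factor, was at 2.59 in ES, -0.78 in the 10-factor clone and -2.48 in the 4-factor clone, and not above background in either 3-factor clone. Sox2 was at 0.18 in ES, 0.56 in the 4-factor clone and -1.86 in the 10-factor clone, and not above background in either 3-factor clone or in MEF. Klf4 was bright in all 9 samples, between 2.83 and 4.89. Myc was at 2.04 in MEF and -0.34 in ES, and between -0.99 and 0.1 in the iPS clones. Whether the probes also read transcripts of the viral vectors is not known.

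**Figure D1:**
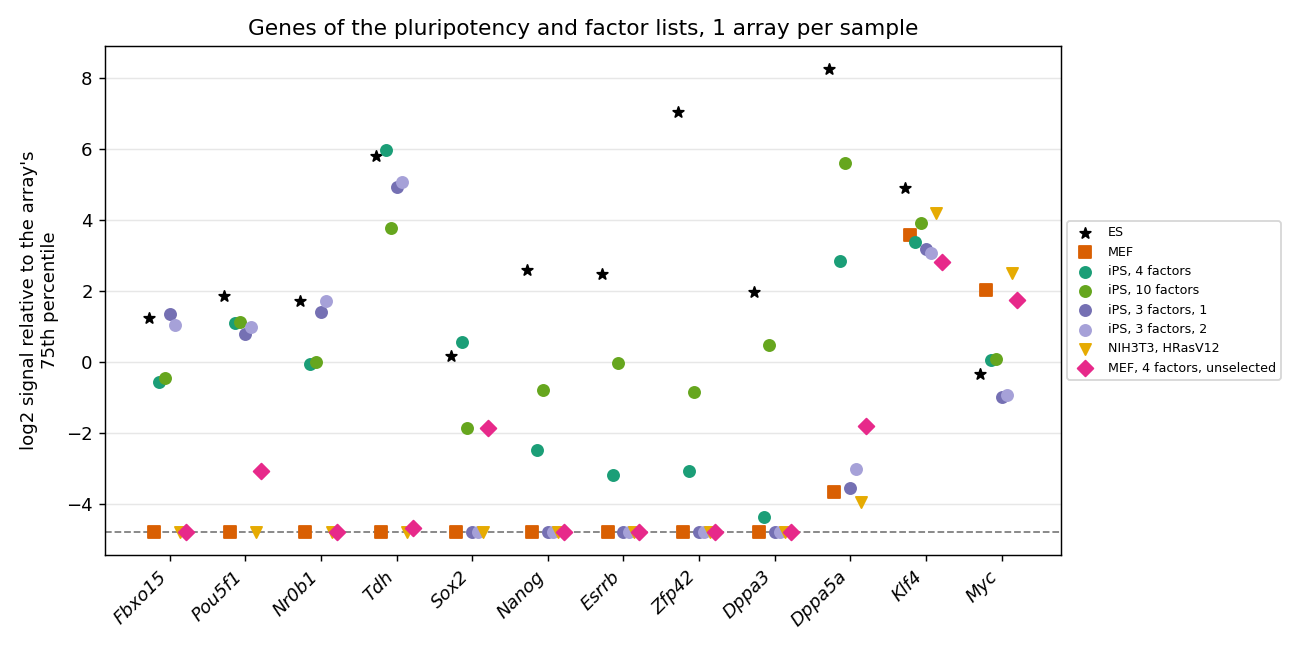
Log2 signal relative to the 75th percentile of each array (vertical axis) for 12 genes of the pluripotency and factor lists, 1 point for each of 8 samples; the dashed line is the floor at -4.78, where values have no order. Fbxo15, Pou5f1, Nr0b1 and Tdh lie above -1 in all 4 iPS clones, while Nanog, Esrrb and Zfp42 lie at the floor in both 3-factor clones.

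The iPS clones correlated with ES slightly more than with MEF. Across 14989 probes the mean Pearson's r of the 4 clones was 0.914 with ES and 0.902 with MEF, a difference of 0.012, while ES and MEF correlated at 0.871 and the clones with each other at a mean of 0.964. The r with ES was 0.933 for the 10-factor clone, 0.908 for the 4-factor clone and 0.904 and 0.91 for the 3-factor clones, and with MEF it was 0.91, 0.897, 0.901 and 0.898. By Spearman's rho 3 of the 4 clones were nearer to ES, the first 3-factor clone being at 0.883 with ES and 0.884 with MEF. In average-linkage clustering ES joined the 4 clones at r = 0.914, apart from the fibroblast-derived samples. These correlations are across genes, which are not independent replicates. The 2 clones made with 3 factors were close to each other (r = 0.994). The robust SD of their log2 difference over 3496 bright probes was 0.19, against 0.15 given by repeated spots and 0.31 to 0.41 for the other pairs of clones. They differed in Xist, the RNA that coats the inactive X chromosome, at 1.39 in clone 2 and not above background in clone 1, and in the homeobox gene Rhox5, at 3.32 in clone 1 and 5.26 in clone 2, so both were kept as samples. Counts with this pair averaged as 1 sample stand beside the counts of changed probes against the fibroblast-derived samples, MEF and ES, as an alternative chosen after the data were seen.

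Most probes that set ES apart from MEF on the high side were not at least 5-fold above MEF in the clones. Of 834 probes at least 5-fold higher in ES than in MEF, 33.5% were at least 5-fold above MEF in the 10-factor clone, 24.1% in the 4-factor clone, and 19.8% and 20.6% in the 3-factor clones. All 4 clones shared 87 of them (10.4%), and 56.2% were reached in none of the clones. Tdh (threonine dehydrogenase) and Pipox (a peroxisomal oxidase) were among those shared by all 4 clones. Pipox, unlike Tdh, was at least 5-fold above MEF in the unselected MEF too. The share was 11.6% in the unselected MEF and 3.6% in the NIH3T3 HRasV12 cells. Of 736 probes at least 5-fold lower in ES, between 47.6% and 56.7% were at least 5-fold below MEF in a clone, and 38.2% in all 4. Here the NIH3T3 HRasV12 cells reached 35.9% and the unselected MEF 8.2%. These shares rest on 1 ES and 1 MEF array, have no p-value and share the MEF array. In simulated samples with no change, set against one MEF array, noise put 74.1 probes at least 5-fold higher and a second such sample shared 9.8 of them; on the low side it shared 14.3 of 72.3. The unselected MEF held 97 of the 834 probes and 60 of the 736. For the probes shared by all 4 clones, choosing them against the unselected MEF in place of MEF gave 4.3% on the high side and 19.6% on the low side.

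**Figure D2:**
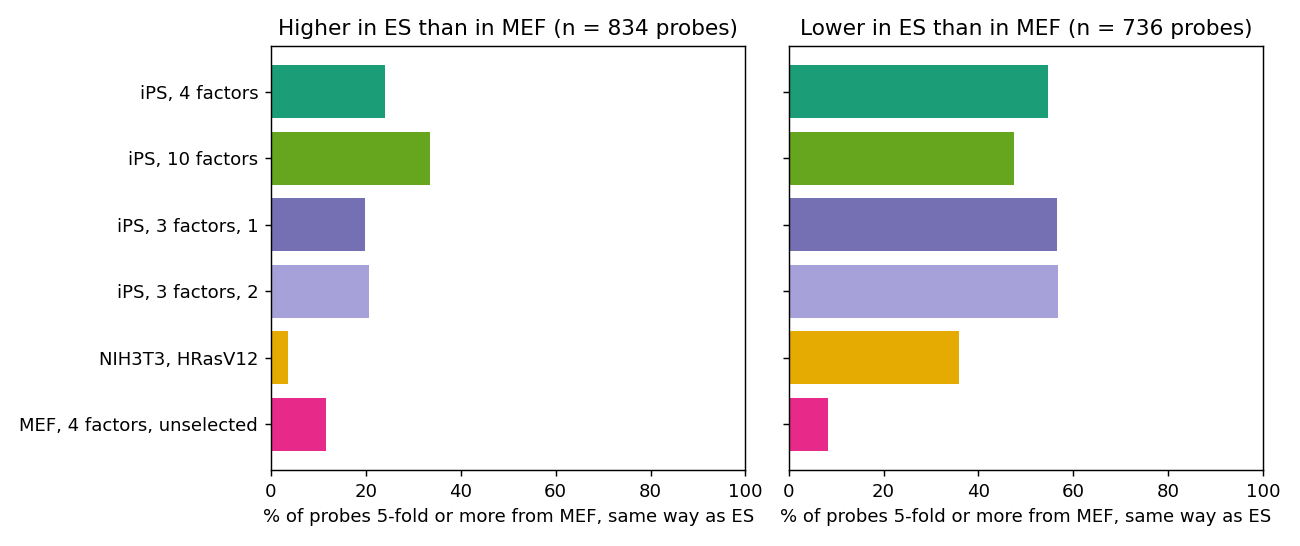
Percent of probes (horizontal axis) at least 5-fold from MEF in the same direction as ES, for 6 other samples, among 834 probes higher and 736 probes lower in ES than in MEF. On the high side the iPS clones reach 19.8% to 33.5%; on the low side they reach 47.6% to 56.7% and the NIH3T3 HRasV12 cells 35.9%.

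The iPS clones were set against the 4 fibroblast-derived samples. Slc38a5, an amino acid transporter, was at least 1960-fold higher in the clones, and Tdh at least 1020-fold. These bounds set the mean of the bright samples against the lowest signal that was well above background on the dim arrays. Pou5f1 rose by 5.36 ± 0.41 (log2, SE, n = 4 and 4). Nup210, a nuclear pore protein, rose by 6.35 ± 0.59, and so did Lrmp (7.26), the adhesion glycoprotein gene Smagp (6.52) and Serpina1d (6.3). The kallikrein protease genes Klk1, Klk1b5, Klk1b3 and Klk1b7-ps rose by 6.15 to 7.43. They are close relatives, and whether their probes share signal was not tested. Of the fibroblast-derived samples only the unselected MEF had Pou5f1, Nup210, Lrmp, Klk1, Klk1b5 and Klk1b3 above background, and only the NIH3T3 HRasV12 cells had Serpina1d; the others stood at or near the floor. On the low side were the collagen genes Col1a2 (-4.6 ± 0.6), Col3a1 (-4.7 ± 1.02) and Col2a1 (-4.39 ± 1.03), the matrix protein gene Thbs2 (-5.73 ± 0.52), the growth factor receptor gene Pdgfrb (-4.29 ± 0.87), and genes of the secreted Dickkopf family, Dkk3 (-6.44 ± 1.03) and Dkk2 (at least 32.2-fold lower). Olfml3 (-4.43) and the adhesion gene Alcam (-4.27) also fell. The calls lost in more than 1 in 3 alternatives were those of Col2a1 (12 of 21) and Col3a1, Olfml3 and Pdgfrb (9 of 21 each). In limma, with Benjamini-Hochberg adjusted p under 0.05, 1154 of 12939 probes changed, 542 higher and 612 lower. With the 3-factor pair averaged, 458 changed (245 and 213), and treat at a fold of 2 called 129 (91 and 38). Only scan 1 holds both classes, so with scan as a block the difference is that of the 4- and 10-factor clones from MEF, as within scan 1, and the other samples add only to the spread. With the block there were 739, of which 273 are among the 1154, and within scan 1 limma called 0 with 2990 at an unadjusted p under 0.05. Scaling to the median gave 284 higher and 694 lower, with a median over all probes of -0.27.

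Of 23 gene lists fixed beforehand, 7 differed between the clones and the fibroblast-derived samples in camera with its preset correlation. The pluripotency list was higher, with a median of 1.58: 9 of its 31 tested members rose, 1 fell and 21 did not pass, and 10 rose when adjusted over the list alone (camera adjusted p = 2.42e-07, adjusted p = 0.488 with an estimated correlation). Nr0b1 rose at least 59.6-fold and Fbxo15 at least 44.5-fold, while the secreted protein gene Spp1 fell by 1.86. The selection marker sits in Fbxo15, so selection favoured cells in which that gene was active. Whether this probe reads the transcript that was selected for is not known. Of the epithelial list (median 2.69), 6 of 17 members rose and 11 did not pass, and 6 rose adjusted over the list alone (camera adjusted p = 6.07e-06, adjusted p = 0.488 with an estimated correlation). Cdh1 (E-cadherin) rose by 5.82 ± 0.71 and Epcam by 5.31 ± 1.09, with only the unselected MEF above background on the fibroblast side. Of the list of chromatin genes of ES cells (median 0.87), 5 of 22 rose and 17 did not pass, and 6 rose adjusted over the list alone (camera adjusted p = 8.86e-05, adjusted p = 0.488 with an estimated correlation). Among them were Jarid2 (2.94) and Tet1 (1.58). The fibroblast matrix list had a median of -2.23: 16 of 44 members fell, none rose and 28 did not pass, and 23 fell adjusted over the list alone (camera adjusted p = 3.56e-11, adjusted p = 0.488 with an estimated correlation). The list of mesenchymal transcription factors had a median of -2.56: 9 of 21 fell and 12 did not pass, and 14 fell adjusted over the list alone (camera adjusted p = 5.53e-07, adjusted p = 0.146 with an estimated correlation). Twist1 fell by 3.23 and Prrx1 by 4.16. In the list of Myc targets (median 0.38) 1 of 29 rose, Tert, also adjusted over the list alone (camera adjusted p = 0.0257, adjusted p = 0.837 with an estimated correlation). In the proliferation list (median 0.58) none of 30 passed, nor adjusted over the list alone (camera adjusted p = 0.0162, adjusted p = 0.856 with an estimated correlation). In fry 6 lists were called, 5 of them among the 7, without Myc targets (fry adjusted p = 0.282) and proliferation (0.51) and with X and Y genes (0.0437). With scan as a block, which sets the 4- and 10-factor clones against MEF alone and so is no check of 4 against 4 samples, the medians were 2.84 for pluripotency, 3.44 epithelial, 1.21 chromatin, -3.34 matrix, -2.86 mesenchymal, 0.49 Myc targets and 0.99 proliferation, and within scan 1 they were 2.54, 2.25, 1.21, -3.34, -2.86, 0.49 and 0.99. Of the 35 ways to split these 8 samples into 4 and 4, 19 called at least 7 lists, the real one included. Some of these keep most clones on one side, so this number is no measure of chance.

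The clones were then set against MEF alone, the parental cell type. Itga11, a collagen-binding integrin gene, was at least 309-fold lower and Fibin at least 288-fold. The matrix genes Postn (-8.44 ± 0.76) and Mfap2 (-8.15 ± 0.29), and the contractile genes Cnn1 (-8.32 ± 1.36), Myl9 (-8.38 ± 0.94) and Tagln (-7.23 ± 0.89), fell, as did Lrrc17 (-8.79) and Dkk3 (-8.01). Mfap2 was above background in 1 of the 4 clones, and Postn and Lrrc17 in 3. Tdh was at least 965-fold higher, Nup210 at least 144-fold, Pipox at least 126-fold and Fgfbp1 at least 102-fold. Klk1b5, Klk1, Klk1b7-ps and Klk1b3 were at least 405-, 377-, 295- and 125-fold higher. Pkp1, a desmosome gene, rose by 6.57 ± 0.5 and Smagp by 6.98 ± 0.56. The calls lost in more than 1 in 3 alternatives were those of Fgfbp1 (10 of 17), Klk1b3 (9 of 17), Cnn1 (9 of 18), Pipox (8 of 17), Tagln (8 of 18), Klk1b5 (7 of 17) and Myl9 (7 of 18). The SE here comes from the 4 clones, and the lone MEF array is assumed to vary like them. In limma 1830 of 13042 probes changed, 614 higher and 1216 lower. Of the lower ones, 409 were at the floor in all 4 clones, where the values show no spread. The count was 873 without floor probes, 351 (53 and 298) with the 3-factor pair averaged, 198 with the spread pooled over more arrays, and 1724 with scan as a block. Within scan 1 limma called 0, with 2990 at an unadjusted p under 0.05. Scaling to the median gave 271 higher and 978 lower.

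Of the 23 lists 11 differed between the clones and MEF in camera. The fibroblast matrix list fell furthest (median -3.31): 25 of 44 members fell and 19 did not pass, and 33 fell adjusted over the list alone (camera adjusted p = 1.56e-14, adjusted p = 0.43 with an estimated correlation). Col1a1 fell by 6.99 ± 0.62. Of the mesenchymal transcription factors (median -2.9) 9 of 21 fell and 12 did not pass, and 13 fell adjusted over the list alone (camera adjusted p = 2.36e-05, adjusted p = 0.43 with an estimated correlation). Of the interferon-response list (median -2.28) 14 of 27 fell and 13 did not pass, and 18 fell adjusted over the list alone (camera adjusted p = 1.19e-07, adjusted p = 0.442 with an estimated correlation). This list was below MEF in other samples too, with medians of -1.97 in ES, -1.5 in the unselected MEF and -3.77 in the NIH3T3 HRasV12 cells, each at percentile 0 of matched random lists. It was not called between the clones and ES (camera adjusted p = 0.778, adjusted p = 0.957 with an estimated correlation), so the lone MEF array stands high here. Isg15 fell by 5.5 ± 0.7 and Usp18, above background in 3 of the 4 clones, by 5.42 ± 0.21. Of the HOX list (median -1.14) 10 of 23 fell and 13 did not pass, and 12 fell adjusted over the list alone (camera adjusted p = 2.36e-05, adjusted p = 0.338 with an estimated correlation). Hoxb6, above background in 2 of the 4 clones, fell by 4.31 ± 0.72 and Hoxa5 by 1.43 ± 0.26, while Hoxa7 differed by -0.82 ± 0.67 and did not pass. The HOX list was below MEF in the unselected MEF too (-0.86, percentile 0), and stood at -0.6 (percentile 11.7) in the NIH3T3 HRasV12 cells. Against all 4 fibroblast-derived samples the clones' HOX list was not called (median -0.55, camera adjusted p = 0.394, adjusted p = 0.875 with an estimated correlation). In the list of markers of other cell types (median -0.45) 4 of 16 fell, 1 rose and 11 did not pass, and 5 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0302, adjusted p = 0.48 with an estimated correlation). On the high side the proliferation list had a median of 0.92: 6 of 30 rose and 24 did not pass, and 20 rose adjusted over the list alone (camera adjusted p = 4.72e-08, adjusted p = 0.48 with an estimated correlation). Mki67 rose by 0.95 ± 0.12 and the replication gene Mcm7 by 1.47 ± 0.27. Of the pluripotency list (median 1.58) 4 of 31 rose, among them Pou5f1, Tdh and Nr0b1, 27 did not pass, and 5 rose adjusted over the list alone (camera adjusted p = 0.00433, adjusted p = 0.608 with an estimated correlation). Fbxo15 itself was at least 40.2-fold higher and did not pass (limma adjusted p = 0.052). The epithelial list (median 2.48) had 2 of 19 higher, Cdh1 and Lsr, also adjusted over the list alone (camera adjusted p = 0.0101, adjusted p = 0.718 with an estimated correlation). The chromatin list (median 1) had 3 of 22 higher, among them Ezh2 and Uhrf1, and 5 adjusted over the list alone (camera adjusted p = 0.000161, adjusted p = 0.43 with an estimated correlation). The Myc target list (median 0.63) had 2 of 29 higher and the glycolysis list (median 0.43) 1 of 19, Pfkp, with the same numbers adjusted over the list alone. Their camera adjusted p were 0.000369 and 0.0204, and the adjusted p were 0.608 and 0.593 with an estimated correlation. The glycolysis list was above MEF in the unselected MEF (1.03) and the NIH3T3 HRasV12 cells (1.02) too. Proliferation (1.07), Myc targets (0.68) and chromatin genes (0.49) were above MEF in the NIH3T3 HRasV12 cells, but not in the unselected MEF (-1.08, 0 and -0.74). The epithelial list was above MEF in the unselected MEF (2.09) but not in the NIH3T3 HRasV12 cells (-1.62). In fry 11 lists were called, 7 of them among these 11, without pluripotency (fry adjusted p = 0.0622), epithelial genes (0.207), Myc targets (0.108) and glycolysis (0.0622) and with neural (0.00596), primitive endoderm (0.00531), transduced factors (0.0158) and X and Y genes (0.0159). With scan as a block, where the difference is again that of the 4- and 10-factor clones, the medians were -3.34 for matrix, -2.86 mesenchymal, -2.27 interferon, -1.13 HOX, -0.37 other cells, 0.99 proliferation, 2.84 pluripotency, 2.94 epithelial, 1.21 chromatin, 0.49 Myc targets and 0.32 glycolysis. Within scan 1 they were -3.34, -2.86, -2.27, -1.03, -0.31, 0.99, 2.54, 2.25, 1.21, 0.49 and 0.32. The calls of the glycolysis list and the list of other cells were lost in both (camera adjusted p = 0.067 with the block in each, and 0.0692 and 0.122 within scan 1).

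**Figure D3:**
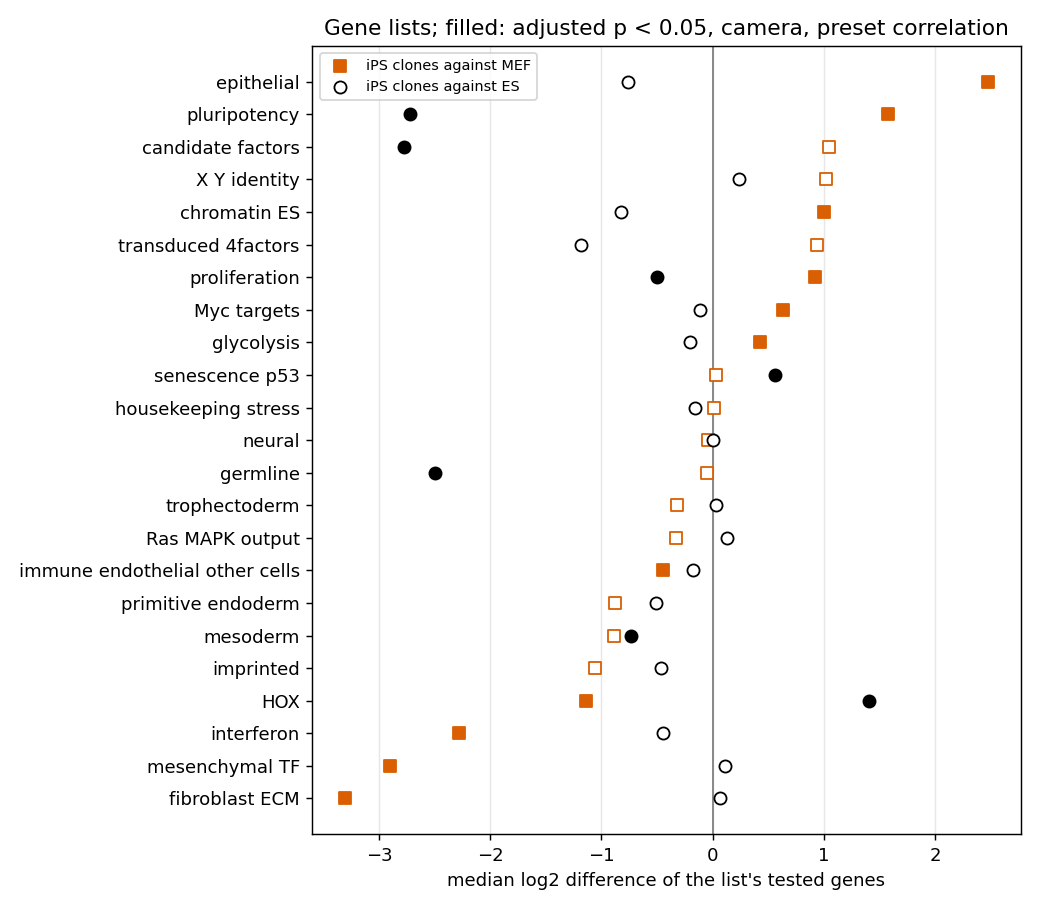
Median log2 difference (horizontal axis) of the tested members of each of 23 gene lists, for the 4 iPS clones against MEF (squares) and against ES (circles); filled points have a camera adjusted p under 0.05 with the preset correlation, and none has with an estimated one. The HOX list lies at -1.14 against MEF and 1.41 against ES. Against all 4 fibroblast-derived samples, not drawn here, it was at -0.55 and not called (camera adjusted p = 0.394).

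The clones were also set against ES. Zfp42 (Rex1), a marker of ES cells, was lower by a log2 difference of -10.4 ± 1.86, measured in the 4- and 10-factor clones and not above background in the 3-factor clones. The germ cell genes Stra8 (-7.42 ± 1.31), Aurkc (-7.16 ± 0.65), Syce1 (-6.32 ± 0.62) and Tex14 (-5.72 ± 0.87) fell, and so did Tekt1, Calb2 and Cela2a (-6.03, -5.61 and -6.05). Aurkc was above background in all 4 clones, Tekt1 in 2, and the other 5 only in the 10-factor clone. Nlrp14 and Sult6b1 were at least 64.8-fold and 57.3-fold lower. On the high side Pkp1 was at least 108-fold above ES, the chloride channel gene Ano1 at least 70.1-fold, the AP-1 gene Fosb at least 38.9-fold, Aox3 at least 33-fold and Tmem238 at least 24.2-fold. The laminin gene Lama4 (5.86 ± 0.8), the chemokine gene Cxcl1 (5.71 ± 0.39), Klk1 (4.74 ± 0.87), Palmd (4.66 ± 0.54) and the homeobox gene Vax2 (4.57 ± 0.64) rose. The calls lost in more than 1 in 3 alternatives were those of Klk1 (12 of 18), Stra8 (10 of 17), Aox3, Zfp42 and Tex14 (9 of 17 each), Lama4 and Vax2 (9 of 18 each), Ano1 (8 of 17) and Palmd (7 of 18). Again the lone ES array is assumed to vary like the clones. In limma 1777 of 13200 probes changed, 533 higher and 1244 lower, and 520 of the lower ones were at the floor in all 4 clones. The count was 595 without floor probes, 503 (67 and 436) with the 3-factor pair averaged, 330 with probes well above background on every array, where more were higher than lower (192 and 138), 890 with the spread pooled, 493 with normexp background correction and 1755 with scan as a block. Within scan 1 limma called 0, with 2917 at an unadjusted p under 0.05. Scaling to the median gave 1012, with a median over all probes of 0.27.

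Of the 23 lists 7 differed between the clones and ES in camera. The germ cell list (median -2.5) had 12 of 21 members lower and 9 that did not pass, and 15 lower adjusted over the list alone (camera adjusted p = 3.94e-08, adjusted p = 0.479 with an estimated correlation). Dazl, above background in 1 of the 4 clones, fell by 3.83 ± 0.17. The pluripotency list (median -2.72) had 4 of 34 lower and 30 that did not pass, and 5 lower adjusted over the list alone (camera adjusted p = 0.000153, adjusted p = 0.826 with an estimated correlation). Tcl1, above background in 3 of the 4 clones, fell by 4.11 ± 0.57, while Nanog differed by -5.8 ± 1.94 and Pou5f1 by -0.86 ± 0.16, and neither passed. The list of candidate factors for reprogramming (median -2.78) had 2 of 20 lower, Tcl1 and Zfp42, and 3 adjusted over the list alone (camera adjusted p = 0.0081, adjusted p = 0.826 with an estimated correlation). Tcl1 is a member of the pluripotency list too, so the calls of these lists are not independent. The proliferation list (median -0.5) had 6 of 30 lower, also adjusted over the list alone, among them Mcm2 (-1.67 ± 0.21) and Top2a (-1.51 ± 0.2) (camera adjusted p = 0.00705, adjusted p = 0.855 with an estimated correlation). The mesoderm list (median -0.73) had 3 of 9 lower and 5 adjusted over the list alone (camera adjusted p = 0.0201, adjusted p = 0.479 with an estimated correlation). Among them was Tal1, at least 4.53-fold lower. The HOX list was higher (median 1.41, 11 of 12 members positive): Hoxa5 rose by 1.5 ± 0.26, 11 members did not pass, and 3 rose adjusted over the list alone (camera adjusted p = 0.00727, adjusted p = 0.479 with an estimated correlation). Hoxa7 was higher by 3.34 ± 0.67 and did not pass over all genes (limma adjusted p = 0.0589). In the list of senescence and p53 genes (median 0.56) 2 of 22 rose, also adjusted over the list alone, the cell cycle inhibitor genes Cdkn2a (3.11 ± 0.39) and Cdkn1a (2.29 ± 0.24) (camera adjusted p = 0.0212, adjusted p = 0.826 with an estimated correlation). In fry 6 lists were called, 4 of them among the 7, without proliferation (fry adjusted p = 0.123), candidate factors (0.102) and senescence and p53 (0.144) and with primitive endoderm (0.00354) and other cell types (0.00345). With scan as a block, where the difference is again that of the 4- and 10-factor clones, the medians were -2.33 for germ cells, -2.14 pluripotency, -1.79 candidate factors, -0.37 proliferation, -0.63 mesoderm, 1.2 HOX and 0.61 senescence, and within scan 1 they were -2.28, -2.13, -1.79, -0.37, -0.5, 0.8 and 0.61. The calls of mesoderm and senescence were lost in both (camera adjusted p = 0.0555 in each with the block, and 0.0897 and 0.0626 within scan 1).

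Clones made with 3 factors were set against those made with 4 and 10 factors, 2 against 2. Ooep, an oocyte gene, was at least 81-fold lower in the 3-factor clones. Cpsf4l fell by 5.37 ± 0.08 and was above background in 1 of the 3-factor clones, with both at the floor value (limma adjusted p = 0.0473 for each gene). They were the only 2 of 13544 probes that passed, with 3072 at an unadjusted p under 0.05, and neither passed with the floor divided by 4, where limma called 0. The call of Ooep was lost in 9 of 13 alternatives and that of Cpsf4l in 8 of 13. Normexp background correction gave 386 probes, and pooling the spread with the fibroblast-derived samples gave 126. The 3-factor clones shared scan 2 and the others scan 1, so factor number and scan cannot be told apart. Of the lists 9 differed in camera and 0 with an estimated correlation or in fry. The pluripotency list was lower (median -1.62), with 0 of 34 members past the threshold, and 9 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.000485, adjusted p = 0.828 with an estimated correlation). Dppa5a differed by -7.5 ± 1.15, Tfcp2l1 by -4.96 ± 0.53 and Klf2 by -2.36 ± 0.36, while Fbxo15 (1.71 ± 0.15) and Nr0b1 (1.59 ± 0.14) were higher. The candidate factors (-1.4), epithelial genes (-1.34), transduced factors (-0.78), markers of other cell types (-0.64), trophectoderm (-0.54) and proliferation genes (-0.18) had medians below 0. Their camera adjusted p were 0.00111, 0.00111, 0.0221, 0.037, 0.0479 and 0.0297. The Myc targets (0.41, adjusted p = 0.00111) and glycolysis genes (0.3, adjusted p = 0.0479) were higher in camera. In each of these 8 lists no member passed over all genes. Adjusted over the list alone, 3 candidate factors, 5 epithelial, 2 transduced factors and 2 trophectoderm genes were lower, and 1 candidate factor was higher. The candidate factor and pluripotency lists share at least Tcl1, so their calls are not independent. With an estimated correlation the adjusted p was 0.871 for proliferation and 0.828 for each of the other 7. The calls of the proliferation, trophectoderm and glycolysis lists were lost in 6 of 8 alternatives each. That of other cell types was lost in 5 and that of epithelial genes in 3. The calls of pluripotency, candidate factors, transduced factors and Myc targets were lost in 2 each.

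The unselected MEF that received 4 factors held markers of macrophages and of epithelium that were lower or not above background in MEF. The macrophage genes Lyz2 (lysozyme) and Tyrobp were 28.2-fold and 26.7-fold above MEF, Cd68 6.73-fold and Csf1r, the macrophage growth factor receptor, at least 8.08-fold. The keratin gene Krt14 was 26.9-fold higher and Epcam at least 7.98-fold. Crym was at least 693-fold higher, Entpd2 at least 166-fold, Myh2 at least 129-fold, Slurp1 at least 128-fold and the coagulation factor gene F13a1 at least 121-fold. The growth-associated chromatin gene Hmga2 was 17.8-fold lower and the chemokine gene Cxcl10 20.4-fold. Sox2 was at least 8.72-fold and Pou5f1 at least 3.79-fold higher, and Fbxo15 and Nanog were not above background. Of 12389 probes, 430 were at least 5-fold higher and 175 at least 5-fold lower, and normexp background correction gave 113 in all. The list of markers of other cell types had a median of 1.62, above all of 10000 random lists matched on signal (percentile 100), and the epithelial list 2.09 (percentile 100). The glycolysis list stood at 1.03 (percentile 99.8). Proliferation (-1.08), HOX (-0.86), Ras and MAPK output (-0.76) and interferon genes (-1.5) were at percentile 0, while the fibroblast matrix list (0.36) was at 38.8. With 1 array each, and the unselected MEF alone in scan 4, these differences have no replicate check.

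**Figure D4:**
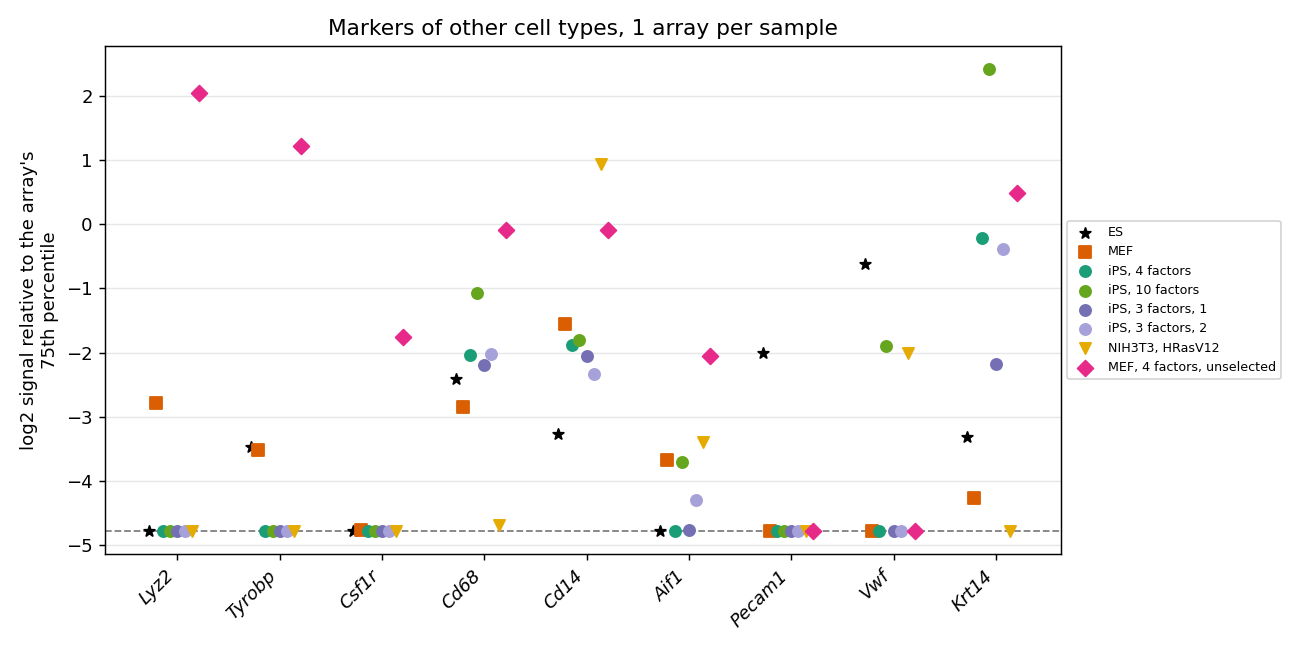
Log2 signal relative to the 75th percentile of each array (vertical axis) for 9 markers of other cell types, 1 point for each of 8 samples; the dashed line is the floor at -4.78. Lyz2 and Tyrobp lie at 2.04 and 1.22 in the unselected 4-factor MEF, while Pecam1 is at the floor there.

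The NIH3T3 HRasV12 cells were lower than MEF in several lists, among them those of fibroblast matrix and imprinted genes. Igf2 and H19, neighbouring imprinted genes, were at least 3920-fold and 858-fold lower than in MEF. The contractile gene Cnn1 was at least 909-fold lower and Col1a1 42.7-fold. The prolactin-related gene Prl2c3 was 71-fold higher, and Dusp6, a phosphatase gene induced by MAPK signalling, 5.82-fold. Cdkn2a was at least 30.6-fold lower. Of 12412 probes 201 were at least 5-fold higher and 720 at least 5-fold lower, and normexp background correction gave 276 in all. The Ras and MAPK output list had a median of 0.68, the proliferation list 1.07 and the glycolysis list 1.02, all at percentile 100 of matched random lists. Myc targets (0.68) were at percentile 99.9. Of 32 compared members of the Ras and MAPK output list, 5 were at least 5-fold higher and 4 at least 5-fold lower. The fibroblast matrix (-2.23), interferon (-3.77), imprinted (-1.65), neural (-1.96), epithelial (-1.62) and senescence and p53 lists (-0.79) were at percentile 0. The cells have other parents than the MEF array and lie in scan 3, so transformation, parent and scan cannot be told apart.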

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

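The tests of fibroblast RNA, of factor number against scan, of single clones and of both explanations for the macrophage markers were chosen after the result was seen, while those of scan for the pluripotency and HOX lists and of other splits of the samples were written before. There were 226 pairs of a named gene and a class of 4 samples. Pairs with no spread were skipped. Classes in which no sample was well above background were skipped too, a choice made after a first run. Fewer than 226 pairs were thus tested. Of these, 44 held a value far from the other 3 by Dixon's criterion, which flags about 1 in 20 groups by chance. In most of the 44 the other samples stood at the floor, which makes any value above it stand apart.

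Among the fibroblast-derived samples the unselected MEF stood apart in 25 genes. These were Pou5f1 (-3.06), Dppa5a (-1.8), Tfcp2l1 (-3.51), Ooep (-1.65), Pipox (0.49), Nup210 (-2.27), Lrmp (-2.96), Klk1 (-0.63), Klk1b5 (-0.65), Klk1b3 (-2.32), Klk1b7-ps (-0.87), Cdh1 (-2.41), Epcam (-1.52), Fgfbp1 (-2.01), Pkp1 (0.7), Aox3 (-3.4), Csf1r (-1.75), Krt14 (0.49), Crym (4.6), Entpd2 (2.58), Myh2 (2.03), Slurp1 (2.02), F13a1 (1.94), Fos (-3.35) and Atf3 (-2.06). The NIH3T3 HRasV12 cells stood apart in Serpina1d (-4.07), Tex14 (-4.68) and Spp1 (7.59), and MEF in Aurkc (-4.64) and Tcl1 (-3.88). Among the iPS clones the 10-factor clone stood apart in Mfap2 (-4.22), Stra8 (-2.16), Syce1 (-3.55), Tex14 (-3.05), Calb2 (-4.38), Cela2a (-4.77), Dazl (-4.47), Cd68 (-1.07), Entpd2 (-3.22) and Cxcl10 (-0.31). The 4-factor clone stood apart in Myh2 (3.26), the first 3-factor clone in Mcm2 (1.34), and the second in Xist (1.39) and Tekt1 (-4.46). Ooep and Cpsf4l differed between the 3-factor and the other clones (-5.73 and -5.37, limma adjusted p = 0.0473 for each), and as the 3-factor clones stood at the floor for both, these differences are taken against the floor.

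The pluripotency list was lower in the 3-factor than in the 4- and 10-factor clones, with a median of -1.62 over 34 members. The median lay at percentile 0 of random lists matched on signal, whose range was -0.27 to 0.16. This cannot decide on a scan difference, as camera had already set the list apart from the other genes of the same arrays. More fibroblast RNA in the 3-factor clones is argued against, as 40 fibroblast matrix genes differed by a median of -0.13 (quartiles -0.44 and 0.32). Factor number and scan cannot be told apart, because 0 scans held clones of both kinds. A difference between single clones stays open: within scan 1 the 10-factor clone exceeded the 4-factor clone by a median of 0.74 over the list, at percentile 100 of random lists (-0.12 to 0.21).

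Macrophage markers were higher in the unselected MEF than in MEF. A scan difference cannot be ruled out: the median of 17 markers of other cell types (1.62) lay at percentile 100 of matched random lists (-0.57 to 0.54), but this is how the pattern was found, and the unselected MEF is alone in scan 4. Macrophage-like cells in that culture stay open as a hypothesis too: 7 macrophage markers had a median of 2.89 (quartiles 2.19 and 3.88) and the 10 other members 0.17. A first run used a smaller set of markers picked by hand after macrophage genes were seen high, and the whole list fixed beforehand replaced it. Whether the factors, the culture or the preparation differed was not tested.

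The HOX list was higher in the iPS clones than in ES. Fibroblast RNA left in the clones is argued against: 36 matrix genes kept a median of 0.24% of the MEF excess over ES (quartiles -0.665 and 5.63), and 8 HOX genes 22.6% (9.16 and 47; permutation p = 0.00287 over 100000 resamples, genes not being independent replicates). A first run on the log2 scale gave 1.35% and 42.7% (permutation p = 0.00274), and the linear scale replaced it because mixing acts on that scale. Both runs take the MEF excess from the lone MEF array, and the HOX list was lower in the unselected MEF than in MEF (-0.86, percentile 0). A scan difference as the whole cause is argued against: within scan 1 the median over 18 members was 0.8, with 16 positive and a bootstrap interval of 0.43 to 1.21, above the range of matched random lists (-0.51 to 0.27). The interval, which reaches under the bound of 0.5 set beforehand, and its reading against random lists were added after the 0.8 was seen, and a scan difference as part of the cause stays open.

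For the clones against the fibroblast-derived samples, 1 of the 35 splits of the 8 samples, the real one, gave as many as 1154 probes. The highest other gave 4. A share of 1 in 35 is the smallest these splits can give, and they treat the 2 close 3-factor clones as separate samples. With that pair averaged the count was 458. Every other split mixes the classes, so the difference between classes enters its spread and lowers its count by construction. The splits thus cannot decide on chance for the count. For the gene lists 19 of the 35 splits gave at least the real 7, and the highest other gave 13. That one had 3 of the 4 clones on one side and so kept part of the real difference. The splits are thus no measure of chance for the number of lists, which stays undecided. The split of scans 1 and 4 without ES against scans 2 and 3 gave 12 lists, and the real comparison with scan as a block gave 10.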

How the results depend on the processing

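Alternatives with floor values divided by 4 or left out, scan 1 alone and the 3-factor pair averaged were chosen after the data were seen, as were median scaling and scan as a block for the gene lists; the others were planned. Of the values of single genes named in these texts, 807 stayed on their side of the threshold or within their spread, 275 kept the direction and no longer passed, 3 moved and none reversed, and causes were not tested except where fewer samples or fewer probes remain by construction. For the clones against fibroblast-derived samples (1154 probes) the count was 641 with no filter on dim probes, 129 with treat at a fold of 2, 739 with scan as a block, 0 in scan 1 alone, 458 with the pair averaged, and 412 to 1587 when samples were left out in turn. Against MEF (1830) it was 947 with normexp, 1074 with the floor divided by 4, 887 with probes well above background on every array, 296 with treat, 873 without floor probes, 0 in scan 1 alone, 351 with the pair averaged, 198 with pooled spread, and 318 to 1895 leaving samples out. Against ES (1777) it was 1012 with median scaling, 493 with normexp, 736 with the floor divided by 4, 330 with every array above background, 318 with treat, 595 without floor probes, 0 in scan 1 alone, 503 with the pair averaged, 890 with pooled spread, and 475 to 2082 leaving samples out. For 3-factor against other clones (2) it was 7 with quantile normalization, 386 with normexp, 40 with no filter, 126 with pooled spread, and 0 with median scaling, the floor divided by 4, every array above background, eBayes trend and robust, treat, without floor probes and with any sample left out, where a lone sample is assumed to vary like the others. Scan as a block was not run there, as scan and factor number coincide. With an estimated correlation 0 lists were called in each of the 4 comparisons, and fry called 0 for 3-factor against other clones. In the other 3 fry called 6, 11 and 6 lists, of which 5, 7 and 4 are among the 7, 11 and 7 of camera, and scan as a block called 10, 9 and 5. In these 3 comparisons the following list calls were lost in more than 1 in 3 alternatives. They were Myc targets against fibroblast-derived samples (5 of 11), other cell types (6 of 11) and glycolysis (4 of 11) against MEF, and senescence and p53 (6 of 11) and mesoderm (4 of 11) against ES. Normexp gave 113 probes for the unselected MEF (605) and 276 for the HRasV12 cells (921). A 3-fold threshold gave 1654 and 1717, and a 10-fold one 186 and 447. Of genes higher in ES, the share in all 4 clones (10.4%) was 7.3% with normexp, 13.9% at 3-fold and 4.3% chosen against the unselected MEF. Of genes lower in ES (38.2%) it was 34.6% with quantile normalization, 42% at 10-fold and 19.6% chosen against the unselected MEF. The mean r with ES (0.914) was 0.938 with no filter and 0.893 as Spearman's rho, and its excess over MEF (0.012) was 0.032 with every array above background. The other 87 alternatives of these results stayed within the spread or within 1.5 times the count, which does not mean that the same lists or probes were called. Normexp moved the median over all probes to -0.16 against ES and -0.14 for 3-factor against other clones, and median scaling moved the latter to 0.22.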

Other observations

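The tests of the other values in this part were all planned, and the genes named were picked after their values were seen. Fos, Atf3 and Fosb were higher in the 4 iPS clones than in both ES and MEF. Fos, an AP-1 gene, was at least 22.7-fold above MEF (limma adjusted p = 0.00411) and at least 19.8-fold above ES (limma adjusted p = 0.00346). Atf3, a stress-response gene, was at least 17.8-fold above MEF (limma adjusted p = 0.0147) and at least 15.5-fold above ES (limma adjusted p = 0.0129). Fosb stood between 0.07 and 0.86 in the clones, at -4.73 in ES and at -4.69 in MEF. Fos and Atf3 were above background in the unselected MEF too, at -3.35 and -2.06. Egr1 did not pass and differed by -0.37 ± 0.46 from MEF and by 0.4 ± 0.46 from ES (limma adjusted p = 0.626 and 0.635). Mapt, a gene of neuronal microtubules, rose by 4.76 ± 0.4 against MEF (limma adjusted p = 0.0109), while of the 14 tested members of its neural list 1 was higher and 2 were lower (median -0.04, camera adjusted p = 0.558, adjusted p = 0.751 with an estimated correlation, fry adjusted p = 0.00596). Tek, an endothelial receptor gene, was at least 16.6-fold above MEF (limma adjusted p = 0.0436). In the list of markers of other cell types against MEF, 1 of 16 tested members was higher and 4 were lower. Its median was -0.45 (camera adjusted p = 0.0302, adjusted p = 0.48 with an estimated correlation, fry adjusted p = 0.0048).

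H19, an imprinted gene, was at 4.51 in MEF, at -0.43 and -0.31 in the 4- and 10-factor clones, and not above background in the 3-factor clones. Igf2, its imprinted neighbour, was at 6.7 in MEF, -0.49 and 0.32 in the 4- and 10-factor clones, and at the floor in both 3-factor clones. Neither passed for the 3-factor clones against the others (limma adjusted p = 0.0843 for H19 and 0.101 for Igf2). Xist, an X-linked gene, was at 1.39 in the second 3-factor clone, which also had the Y-linked gene Eif2s3y at 0.22, and not above background in the other 3 clones, where Eif2s3y was at 1.28, 1.15 and 0.9. MEF and the unselected MEF had both genes above background, Xist at 0.51 and -0.35 and Eif2s3y at -0.72 and 0.92.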
